A study of Mus musculus with 4 samples.

How the data were processed

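RNA sequencing was carried out on 4 mouse libraries, 2 labelled E4BP4-cKO and 2 labelled wild-type. Per the labels' protocols, naive CD4 T cells were taken from the spleens of C57BL/6 mice and cultured for 3 days under conditions that favour T follicular helper (Tfh) cells, the CD4 T cells that help B cells in germinal centres. The medium held IL-6 and IL-21 at 10 ng/ml each, antibodies against IFN-γ and IL-4 at 10 µg/ml each, and an antibody against TGF-β at 20 µg/ml. Total RNA was extracted with TRIzol and turned into random-primed cDNA of about 200 bp, per the labels' protocols. Groups were taken from the genotype stated in the labels, and replicate numbers from the sample titles. The labels do not say whether the 2 libraries of a group came from separate mice or cultures. The p-values of single genes therefore measure the spread between these libraries. Within each group Xist reads were abundant in 1 library and at most 17 in the other, which repeats of 1 RNA sample would not show. The sources used here do not give the sex of the mice, the Cre driver or the deleted part of the gene.

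The deposited table held whole-number counts of reads per gene, not normalised, for 52636 Ensembl gene IDs in all 4 libraries. The submitters' processing notes name CASAVA, HISAT2 and featureCounts, without versions, and the mouse build mm10. The strand setting, the annotation release and the treatment of reads that fit several genes are not given in the sources used here. Reads of a gene and of an overlapping or near-identical gene can therefore not be told apart in these counts. Of the IDs, 52489 were also in GENCODE release M21 on GRCm38, the same build as mm10, and 49993 of these had the same start, end and strand there. Coordinates are those of the deposited table. Every per-sample column of the table was matched to a sample by its title.

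Total counts were 26579592 and 19057077 in the libraries labelled E4BP4-cKO and 21543872 and 24447091 in those labelled wild-type. A single count corresponded to between 0.0385 and 0.0546 CPM, the count scaled by library size. Floors were set at 3 counts per library, and intervals on counts are at a confidence level of 95%. Intervals and floors cover counting error only. The counts of the 2 libraries within each group differed by more than sampling noise, with a chi-square per degree of freedom of 23.5 for wild-type and 29.9 for E4BP4-cKO, so all 4 were kept as separate libraries.

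CPM values were computed from the deposited counts with TMM scaling factors, which ran from 0.962 to 1.04. Genes were kept with edgeR's filterByExpr on the groups, which left 15503 of the 28039 genes with a count in any library. The comparison of the groups used edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, without a covariate, and two-sided p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05. Log2 fold changes are given as E4BP4-cKO over wild-type with standard errors (SE), and CPM values as mean ± SD of the 2 libraries. An exact permutation test of 2 libraries against 2 cannot go below a two-sided p of 0.333 and was not used.

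Before the data were examined, 30 gene lists, the tests, the alternatives and the rule for named genes were fixed. Each list was tested with limma 3.58.1 (camera, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01), two-sided, with p-values adjusted over the 30 lists. With that preset, camera's p-values rest mainly on the spread over genes, taken as nearly independent. They do not measure the spread between libraries. Beside each list stand the number of its genes called over all genes tested and the number adjusted over the list alone. The lists share 36 genes. The named genes were Nfil3, Bcl6, Cxcr5, Pdcd1, Icos and Il21, whatever their values. To these came the 10 called genes with the largest log2 fold change in each direction that had a mean of at least 1 CPM, groups that did not overlap and an official symbol. Up to 4 members with the lowest p were named from each list discussed, and every gene in a count of 5 or fewer. Some genes that this rule selects are not reported here. Other genes are said to have been chosen after their values were seen.

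The scripts were tested on simulated counts for this comparison, drawn for 15229 genes of which 200 were changed. The edgeR test recovered 31% of genes changed 2-fold and 67% of those changed 4-fold, and 10 of its 108 calls were false. On simulated lists, camera with the preset correlation called 10 of 10 raised lists and 0 of 100 unchanged ones. With an estimated correlation camera called 0 of the 10 raised lists, as did fry. Simulated genes were drawn independently and raised by the same fold. These lists therefore do not show how any of these settings performs where genes move together or change more. In the lists called in the data, estimated correlations ran from -0.0323 (co-inhibitory receptors and Il10) to 0.808 (ribosomal protein genes), with 0.777 for mitotic and S-phase genes.

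Alternatives were DESeq2 size factors, upper-quartile factors or total library size in place of TMM, no filter, a filter of at least 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, edgeR's glmTreat at 1.5-fold, camera with an estimated correlation, fry, and leaving out each library in turn. The lists under DESeq2 size factors and upper-quartile factors were added after seeing the data. Figures were drawn with matplotlib 3.10.9.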

Results

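The data comprised 4 RNA-seq libraries of mouse CD4 T cells cultured under Tfh-polarising conditions, 2 labelled E4BP4-cKO and 2 labelled wild-type. E4BP4 is the transcription factor encoded by Nfil3, and cKO stands for a conditional knockout. The comparison asked which genes differ in RNA level between Tfh-polarised cells with and without E4BP4. Depth was similar across libraries, from 19057077 to 26579592 counts, with 22158 to 23575 genes detected. The 2 groups separated on the first principal component, which held 73.9% of the variance, and the second held 13.7%. Across genes, log2 CPM values correlated at r = 0.979 and r = 0.982 within groups and between 0.928 and 0.945 across groups, where genes are not independent replicates.

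Nfil3, the targeted gene, went against the direction expected from the labels in every library. It had 4649 and 3965 counts in the libraries labelled E4BP4-cKO and 290 and 377 counts in those labelled wild-type. This corresponded to 198 ± 26.6 CPM against 14.03 ± 1.09 CPM (mean ± SD, n = 2 each), a log2 fold change of 3.81 (SE 0.15, adjusted p = 0.00397). Each library labelled E4BP4-cKO stood between 12.1 and 16.3 times above each library labelled wild-type. Nfil3 (ENSMUSG00000056749) lies on the minus strand of chromosome 13 from 52967209 to 52981073 in mm10. In the annotation it has 2 exons, exon 1 from 52980861 to 52981073 and exon 2 from 52967209 to 52969021, and its whole coding sequence lies in exon 2, from 52967481 to 52968866. The deposited values are 1 count per gene over both exons, and the deleted part is not given in the sources used here, so these counts do not show which exon the reads came from. The RNA of the targeted gene thus ran against the direction expected from the labels. Groups are therefore named by their labels throughout, and no direction below is to be read as an effect of losing E4BP4.

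**Figure D1:**
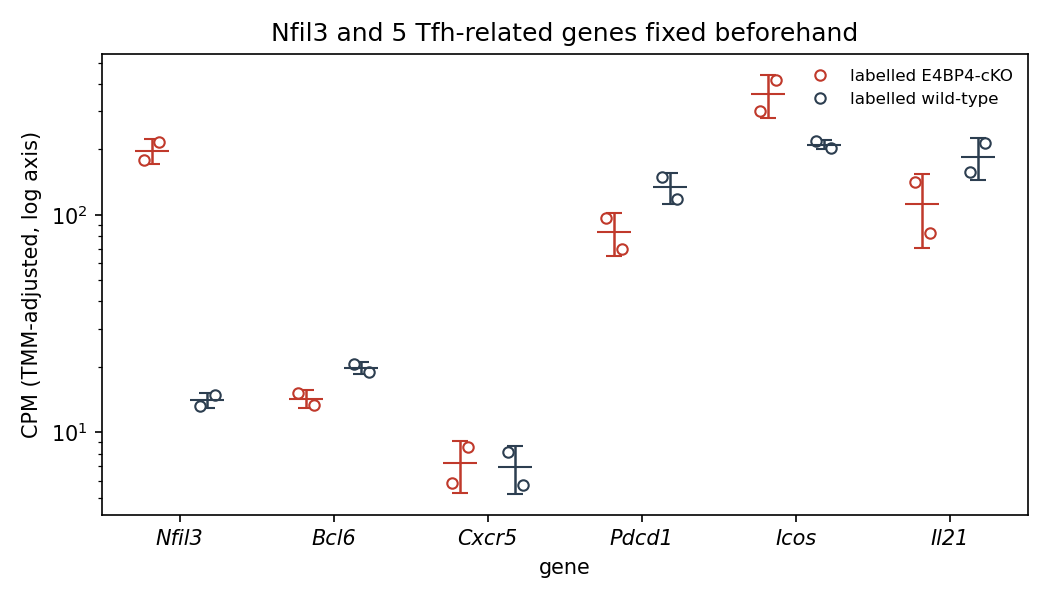
CPM of Nfil3 and 5 Tfh-related genes on a log axis, by gene, with each library as an open circle, the mean as a horizontal bar and the SD as an error bar (n = 2 per group). Nfil3 stood at 179 and 216 CPM in the libraries labelled E4BP4-cKO and at 13.3 and 14.8 CPM in those labelled wild-type, while the groups overlapped for Cxcr5.

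Across all genes, 1191 were higher and 1013 lower in the libraries labelled E4BP4-cKO, together 14.2% of the 15503 tested. Of these, 799 were higher and 428 lower at least 2-fold, and 204 were higher and 95 lower at least 8-fold. Among the 10 genes named for the largest increases, Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254), stood at 144 ± 13.6 against 1.55 ± 0.853 CPM, a log2 fold change of 6.56 (SE 0.34, adjusted p = 0.00822). Ptgs2, the inducible cyclooxygenase, stood at 94.99 ± 18.4 against 2.03 ± 0.816 CPM (log2 fold change 5.56), and Il1a, which encodes the cytokine interleukin-1α, at 38.1 ± 18.5 against 0.846 ± 0.0314 CPM (log2 fold change 5.49). Crisp1, at 11.5 ± 2.51 CPM, and the mast cell tryptase gene Tpsg1, at 6.02 ± 3.72 CPM, were near the floor in the libraries labelled wild-type, with 4 and 5 counts there in all. Fpr2, a formyl peptide receptor gene, had 85 and 89 counts in the libraries labelled E4BP4-cKO and 0 in both others, which makes it at least 31.9-fold higher against a floor of 3 counts per library. For 4 further genes the libraries labelled wild-type held 1 to 3 counts in all. The ratio of the pooled levels was 201 for the water channel gene Aqp8 (95% exact counting interval 35.6 to 7975), 166 for Vnn3 (56.3 to 806), 124 for Wfdc17 (34.1 to 1034) and 50.2 for the Fc receptor gene Fcgr1 (13.5 to 421). The myeloid genes Cd14, at 46.2 ± 26.8 against 1.84 ± 0.765 CPM, and Cd68, at 33.8 ± 9.51 against 5.28 ± 1.58 CPM, were higher in the same libraries.

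The largest decreases were in genes of varied function. Myh11, a smooth muscle myosin heavy chain gene (chromosome 16, 14194527 to 14291408), stood at 0.189 ± 0.113 CPM in the libraries labelled E4BP4-cKO against 8.53 ± 0.753 CPM, a log2 fold change of -5.38 (SE 0.43, adjusted p = 0.0141). Wnt3, a Wnt ligand gene, stood at 0.631 ± 0.739 against 17.3 ± 10.6 CPM (log2 fold change -4.66; not called with limma-voom, adjusted p = 0.0513) and Vat1l at 0.620 ± 0.646 against 17.5 ± 5.20 CPM (log2 fold change -4.71). Galnt14, which encodes a glycosyltransferase, stood at 0.516 ± 0.575 against 10.2 ± 0.266 CPM, Zbtb7c at 0.2499 ± 0.353 against 5.46 ± 0.158 CPM (not called with DESeq2, adjusted p = 0.0949), and the polarity gene Pard3 at 0.104 ± 0.0702 against 2.51 ± 0.386 CPM. Cxcl13, which encodes the chemokine ligand of Cxcr5, had 5 and 0 counts in the libraries labelled E4BP4-cKO and 121 and 59 in the others (log2 fold change -5.09, adjusted p = 0.0330). The chemokine gene Ccl1 had 2 counts in all in the libraries labelled E4BP4-cKO, and the libraries labelled wild-type were 60.4 times higher (16.4 to 504, 95% exact counting interval). For Slc25a48, with 3 counts, that ratio was 30.9 (10.3 to 152). Pcna-ps2 (log2 fold change -5.13) is a near-identical copy of Pcna, so its count is uncertain. Of the exon bases of Tpsg1 and Il1a, 11.4% and 11.2% are also covered by an antisense gene.

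These counts moved with the libraries and the scaling. Without E4BP4-cKO replicate 2, 246 genes were higher and 74 lower, without wild-type replicate 1, 528 and 175, and under scaling to total library size, 1033 were higher and 1636 lower. Of the 104 called genes that the naming rule selected besides Nfil3, 61 lost their call without E4BP4-cKO replicate 2, 51 without wild-type replicate 1, 22 without E4BP4-cKO replicate 1 and 21 without wild-type replicate 2, and none of these 104 changed sign in the reduced fits.

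The Tfh genes themselves moved apart. Of the 26 tested genes of the fixed Tfh programme, 3 were higher and 8 lower in the libraries labelled E4BP4-cKO (4 and 12 adjusted over the list alone), and camera called the list lower (adjusted p = 0.0248; adjusted p = 0.704 with an estimated correlation). The 8 lower genes were Cd40lg, the ligand through which T cells stimulate B cells, the coactivator gene Pou2af1, the receptor genes Btla, Slamf6 and Il6ra, the transcription factor genes Lef1 and Tox, and Angptl2. Cd40lg stood at 35.8 ± 2.24 against 68.2 ± 0.393 CPM (log2 fold change -0.93, SE 0.11), Btla at 106 ± 40.0 against 345 ± 12.0 CPM (-1.70, SE 0.27) and Pou2af1 at 15.9 ± 3.95 against 126 ± 53.8 CPM (-2.98, SE 0.35). The 3 higher genes were Il4, Stat3 and Icos, of which Il4 had a log2 fold change of 2.08 (SE 0.33, adjusted p = 0.0287). Without E4BP4-cKO replicate 2, 0 genes of the list were higher and 2 lower, without wild-type replicate 1, 1 and 4, and without wild-type replicate 2, 0 and 7. B cells also express Pou2af1 and Btla, and the B cell genes Ighm, at 33.3 ± 14.3 against 242 ± 1.17 CPM, and Igkc were lower in the same libraries.

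Of the 5 Tfh-related genes fixed by name, only Icos was called by edgeR with all 4 libraries, TMM factors, filterByExpr and no covariate. This costimulatory receptor gene stood at 359 ± 81.1 against 210 ± 10.2 CPM (log2 fold change 0.77, SE 0.18, adjusted p = 0.0485). Bcl6, the transcription factor that directs Tfh differentiation, had a log2 fold change of -0.47 (SE 0.17, adjusted p = 0.111), Pdcd1, which encodes PD-1, -0.69 (SE 0.20, adjusted p = 0.0710) and the cytokine gene Il21 -0.72 (SE 0.29, adjusted p = 0.141). Cxcr5, the follicle homing receptor gene, stood at 7.21 ± 1.93 and 6.93 ± 1.70 CPM, a difference smaller than the spread between libraries (log2 fold change 0.05, SE 0.31, adjusted p = 0.921). Without E4BP4-cKO replicate 1 the Tfh list was no longer called (adjusted p = 0.0674), while Pdcd1 (log2 fold change -0.94, adjusted p = 0.0455) and Il21 (-1.16, adjusted p = 0.0496) were. Both were also called with DESeq2 (adjusted p = 0.0126 and 0.0464). With the replicate number as a block in edgeR, Pdcd1 was called (adjusted p = 0.0271) and Icos was not (log2 fold change 0.75, adjusted p = 0.0561). Icos lost its call without E4BP4-cKO replicate 2 (log2 fold change 0.54, adjusted p = 0.0986), without wild-type replicate 1 (0.82, adjusted p = 0.140), without wild-type replicate 2 (0.72, adjusted p = 0.121) and under scaling to total library size (0.68, adjusted p = 0.0512).

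Most genes of the fixed co-inhibitory list, but not Btla or Pdcd1, were higher in the libraries labelled E4BP4-cKO. In the list of co-inhibitory receptors and Il10, 14 of 18 genes were higher and 1, Btla, was lower (15 and 2 adjusted over the list alone; camera adjusted p = 2.05e-05; adjusted p = 0.704 with an estimated correlation). Pdcd1 had a log2 fold change of -0.69 and was not called over all genes (edgeR adjusted p = 0.0710), but was lower adjusted over the list alone. Procr, the protein C receptor gene, stood at 62.6 ± 15.8 against 3.22 ± 0.937 CPM (log2 fold change 4.27, SE 0.29, adjusted p = 0.0123). Havcr2, which encodes TIM-3, stood at 25.5 ± 4.20 against 3.22 ± 0.616 CPM (2.98, SE 0.24), the receptor gene Cd244 at 30.0 ± 3.72 against 3.43 ± 1.03 CPM (3.13, SE 0.27) and Pdpn, which encodes podoplanin, at 7.93 ± 0.670 against 0.392 ± 0.167 CPM (adjusted p = 0.0159). Il10 was also higher (log2 fold change 1.67, adjusted p = 0.0304). That count of 14 became 8 without E4BP4-cKO replicate 2 and 9 without wild-type replicate 1, and 2 genes were lower without E4BP4-cKO replicate 1. In the same libraries the mast cell gene Cpa3, at 466 ± 139 against 76.9 ± 49.9 CPM, and the myeloid genes Cd14, Fcer1g and Cd68 were higher too.

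The list of STAT3 and cytokine feedback genes had 9 of 19 genes higher and 1, the receptor gene Il6ra, lower (10 and 1 adjusted over the list alone; camera adjusted p = 0.00972; adjusted p = 0.704 with an estimated correlation). The cytokine genes Osm and Lif stood at 237 ± 27.1 against 62.3 ± 7.35 CPM (log2 fold change 1.92, SE 0.15) and at 484 ± 37.9 against 229 ± 10.1 CPM (1.08, SE 0.13). The kinase genes Pim2 and Pim1 had log2 fold changes of 1.96 (SE 0.18) and 1.44 (SE 0.24). In the list of CD8, cytotoxic and NK markers, 7 of 14 genes were higher and 1, the chemokine gene Xcl1, was lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.0150; adjusted p = 0.704 with an estimated correlation). The granzyme genes Gzmb and Gzma stood at 2680 ± 31.2 against 1114 ± 333 CPM and at 190 ± 71.0 against 28.8 ± 14.3 CPM, and the receptor genes Klrk1 and Klrc1 had log2 fold changes of 1.53 (SE 0.20) and 1.52 (SE 0.23). Cd8a, chosen after its values were seen, stood at 7.19 ± 3.76 against 4.25 ± 0.129 CPM and was not called (adjusted p = 0.236). In the STAT3 list 3 genes, and in the cytotoxic list 0, were higher without E4BP4-cKO replicate 2, and 2 and 5 without wild-type replicate 1. In the STAT3 list 0 genes were lower when E4BP4-cKO replicate 2 or either library labelled wild-type was left out, and in the cytotoxic list 0 were lower without wild-type replicate 1. Without E4BP4-cKO replicate 1 the cytotoxic list was no longer called (adjusted p = 0.0724). The mast cell and myeloid genes Cpa3, Cd14, Fcer1g and Cd68 were higher in the same libraries.

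Genes of other helper T cell programmes changed in part. The Th17 programme was called higher (camera adjusted p = 0.0188; adjusted p = 0.728 with an estimated correlation), with 2 of 15 genes higher, the cytokine gene Il22 (log2 fold change 2.52, SE 0.59) and the receptor gene Ahr (1.06, SE 0.25), and 0 lower (4 and 0 adjusted over the list alone). This call was lost without E4BP4-cKO replicate 1 (adjusted p = 0.0724) and without wild-type replicate 1 (adjusted p = 0.129). Il22 was not called under upper-quartile factors (adjusted p = 0.0512), nor Ahr under scaling to total library size (adjusted p = 0.0530). The Treg programme was not called with all 4 libraries, TMM factors and no covariate (camera adjusted p = 0.0802). It was called higher with the replicate number as a block (adjusted p = 0.0357), under scaling to total library size (adjusted p = 0.0496) and without wild-type replicate 2. In it 6 of 17 genes were higher and 2 lower (9 and 2 adjusted over the list alone), among them Foxp3, the regulatory T cell transcription factor gene, at 7.70 ± 3.16 against 1.46 ± 0.260 CPM (log2 fold change 2.38, SE 0.40), and Ebi3 (1.74, SE 0.24), while Socs2 (-2.12, SE 0.15) and Nrp1 (-1.61, SE 0.15) were lower. In the Th1 programme, also not called (camera adjusted p = 0.256), 4 of 17 genes were higher, Il12rb1, Ccl5, Il12rb2 and Runx3, and 4 lower, among them Il18r1, Hlx and Tbx21 (5 and 7 adjusted over the list alone). In the Th2 programme (camera adjusted p = 0.105, and 0.00797 without wild-type replicate 2), Il4 and the receptor gene Il1rl1 were higher among 12 genes and 0 lower (4 and 0 adjusted over the list alone). Without E4BP4-cKO replicate 2, 0 genes were higher in each of the Th17, Treg, Th1 and Th2 programmes, and without wild-type replicate 1, 0, 1, 1 and 2. The Th17 programme had 5 higher without wild-type replicate 2. The Th1 programme had 2 higher and 7 lower without E4BP4-cKO replicate 1, and 2 lower without E4BP4-cKO replicate 2 or wild-type replicate 1. The Th2 programme had 1 gene lower without E4BP4-cKO replicate 1 or wild-type replicate 1. Mast cells and basophils also express Il4 and Il1rl1, and the mast cell gene Cpa3, at 466 ± 139 against 76.9 ± 49.9 CPM, and the myeloid genes Cd14, Fcer1g and Cd68 were higher in the same libraries.

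Cell cycle genes were lower in the libraries labelled E4BP4-cKO. Of the 32 mitotic and S-phase genes, 28 were lower and 0 higher (32 and 0 adjusted over the list alone), with a median log2 fold change of -0.98 (camera adjusted p = 1.50e-12; adjusted p = 0.704 with an estimated correlation). The cyclin gene Ccna2 stood at 69.6 ± 0.555 against 160 ± 34.5 CPM (log2 fold change -1.20, SE 0.17, adjusted p = 0.0255), the replication licensing gene Mcm2 at 127 ± 9.08 against 276 ± 55.2 CPM (-1.12, SE 0.17), and the mitotic genes Cenpf (-0.99, SE 0.14) and Aurka (-0.998, SE 0.15) at about that size. The 4 genes of the list that were not called were Pcna, Ccne1, Ube2c and Ccne2. The number of lower genes was 0 without E4BP4-cKO replicate 2, 10 without wild-type replicate 1 and 17 without E4BP4-cKO replicate 1, while camera called the list in each of these fits. In the same libraries the B cell genes Ighm and Igkc were lower, at 33.3 ± 14.3 against 242 ± 1.17 CPM and 13.7 ± 7.74 against 103 ± 4.41 CPM, and the mast cell gene Cpa3 higher. In the list of the PRC2 complex and class I histone deacetylases, which was not called (camera adjusted p = 0.0873), the methyltransferase gene Ezh2 (-1.30, SE 0.22), Rbbp7 (-0.80, SE 0.12) and Phf19 (-0.93, SE 0.17) were lower and Phf1 (0.91, SE 0.18) and Ezh1 (0.54) higher among 15 genes (2 higher and 7 lower adjusted over the list alone). Of these 15, 0 were called either way without E4BP4-cKO replicate 2 or without wild-type replicate 1, 1 was higher and 3 lower without E4BP4-cKO replicate 1, and 0 were higher and 4 lower without wild-type replicate 2. Replication-dependent histone genes had 0 of 8 called either way and adjusted over the list alone. Their median log2 fold change was 0.13 although camera's direction was down (adjusted p = 0.941).

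Sterol synthesis genes went the other way. Of 23 cholesterol synthesis genes, 9 were higher and 0 lower (14 and 0 adjusted over the list alone), with a median log2 fold change of 0.51 (camera adjusted p = 0.000248; adjusted p = 0.704 with an estimated correlation). They included the synthase gene Hmgcs1 at 260 ± 45.1 against 123 ± 15.6 CPM (log2 fold change 1.08, SE 0.17), Msmo1 (0.95, SE 0.14) and Lss (0.93, SE 0.16). The number of higher genes was 0 without E4BP4-cKO replicate 2, 0 without wild-type replicate 1 and 3 without E4BP4-cKO replicate 1, while camera called the list in each of these fits. Ribosomal protein genes were called higher as a list (median log2 fold change 0.41; camera adjusted p = 2.05e-05; adjusted p = 0.704 with an estimated correlation), with Rps27 (0.72, SE 0.15) and Rpl37 (0.60, SE 0.14) called among 31 and 0 adjusted over the list alone. That count of 2 became 15 without E4BP4-cKO replicate 1, 16 with DESeq2 and 0 without any 1 of the other 3 libraries. Ribosomal protein genes took 7.70% and 8.84% of all counts in the libraries labelled E4BP4-cKO and 6.69% and 6.66% in those labelled wild-type. The mast cell and myeloid genes Cpa3, at 466 ± 139 against 76.9 ± 49.9 CPM, and Cd14, at 46.2 ± 26.8 against 1.84 ± 0.765 CPM, were higher in the same libraries.

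**Figure D2:**
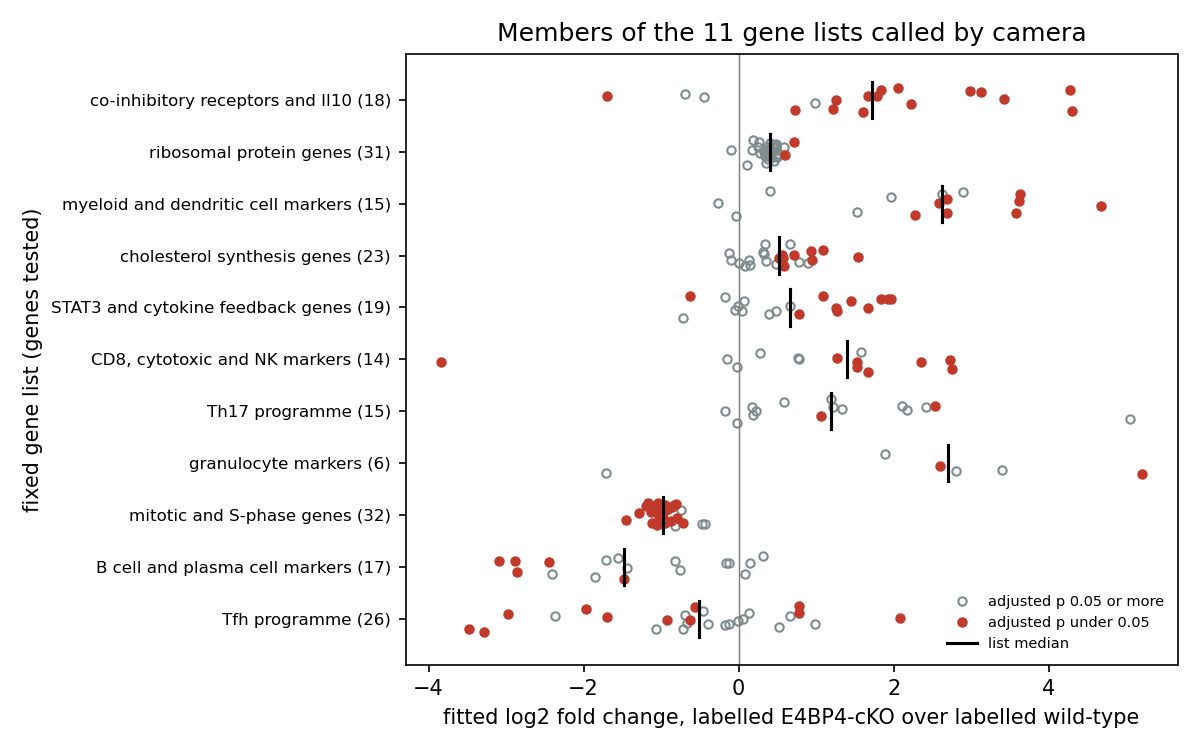
Fitted log2 fold changes (labelled E4BP4-cKO over labelled wild-type) of the members of the 11 gene lists called by camera, 1 row per list with the number of genes tested. Filled points are genes called at an adjusted p under 0.05, open points are not, and black bars mark list medians, which were -0.98 for mitotic and S-phase genes and 1.72 for co-inhibitory receptors and Il10.

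Markers of other cell types also differed between the groups. Of 15 myeloid and dendritic cell markers, 8 were higher and 0 lower in the libraries labelled E4BP4-cKO (12 and 0 adjusted over the list alone; camera adjusted p = 0.000170; adjusted p = 0.704 with an estimated correlation). The macrophage and monocyte genes Cd68 and Cd14 stood at 33.8 ± 9.51 against 5.28 ± 1.58 CPM and at 46.2 ± 26.8 against 1.84 ± 0.765 CPM, the Fc receptor gene Fcer1g at 80.9 ± 13.6 against 12.6 ± 6.08 CPM and the dendritic cell gene Xcr1 at 2.67 ± 0.399 against 0.435 ± 0.162 CPM. Of 6 granulocyte markers, the mast cell gene Cpa3 and Csf3r were higher and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.0220; adjusted p = 0.704 with an estimated correlation). Cpa3 stood at 564 and 368 CPM in the libraries labelled E4BP4-cKO and at 112 and 41.6 CPM in those labelled wild-type (log2 fold change 2.60, SE 0.50, adjusted p = 0.0357). Csf3r had 1 count in all in the libraries labelled wild-type, and the others were 44.9 times higher (95% exact counting interval 7.63 to 1814). The basophil gene Mcpt8 stood at 324 and 229 CPM against 142 and 7.81 CPM and was not called (adjusted p = 0.289). The number of higher myeloid and dendritic markers was 4 without E4BP4-cKO replicate 1 and 3 without E4BP4-cKO replicate 2. For the granulocyte markers it was 1 without E4BP4-cKO replicate 1 and 4 without wild-type replicate 1. The granulocyte list was no longer called without E4BP4-cKO replicate 1 (adjusted p = 0.0949) or with a filter of at least 1 CPM in 2 libraries (adjusted p = 0.0759).

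B cell and plasma cell markers went down. Of 17, 5 were lower and 0 higher (7 and 0 adjusted over the list alone; camera adjusted p = 0.00109; adjusted p = 0.704 with an estimated correlation). The immunoglobulin genes Ighm and Igkc stood at 33.3 ± 14.3 against 242 ± 1.17 CPM and at 13.7 ± 7.74 against 103 ± 4.41 CPM, and Spib (log2 fold change -2.45, SE 0.40), Jchain (-3.09, SE 0.59) and Cd74 (-1.49) were lower too. Activated T cells can also express Cd74. The number of lower genes was 2 without wild-type replicate 1 and 8 without E4BP4-cKO replicate 1. Of the T cell genes Cd3e, Cd4 and Trac, chosen after their values were seen, none was called, with log2 fold changes of -0.03 (adjusted p = 0.924), 0.39 (adjusted p = 0.190) and 0.20 (adjusted p = 0.482). The erythroid and platelet markers were not called as a list with TMM factors and no covariate (camera adjusted p = 0.0873). Among 8 genes, Hbb-bt, Itga2b and Hba-a1 were higher and 0 lower (3 and 0 adjusted over the list alone). The list was called higher with the replicate number as a block (adjusted p = 0.0305) and under scaling to total library size (adjusted p = 0.0496). It was also called without E4BP4-cKO replicate 2 and without wild-type replicate 1. The size of the change in these markers depended on the library left out. The gamma delta T cell markers had 0 of 8 genes called, also adjusted over the list alone (camera adjusted p = 0.941), and of 8 stromal and endothelial markers (camera adjusted p = 0.499) Col1a2 was higher and Cxcl13 lower (2 and 1 adjusted over the list alone). Among these 8, 0 were higher without E4BP4-cKO replicate 1 or wild-type replicate 2, and 0 lower without E4BP4-cKO replicate 2 or wild-type replicate 1.

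**Figure D3:**
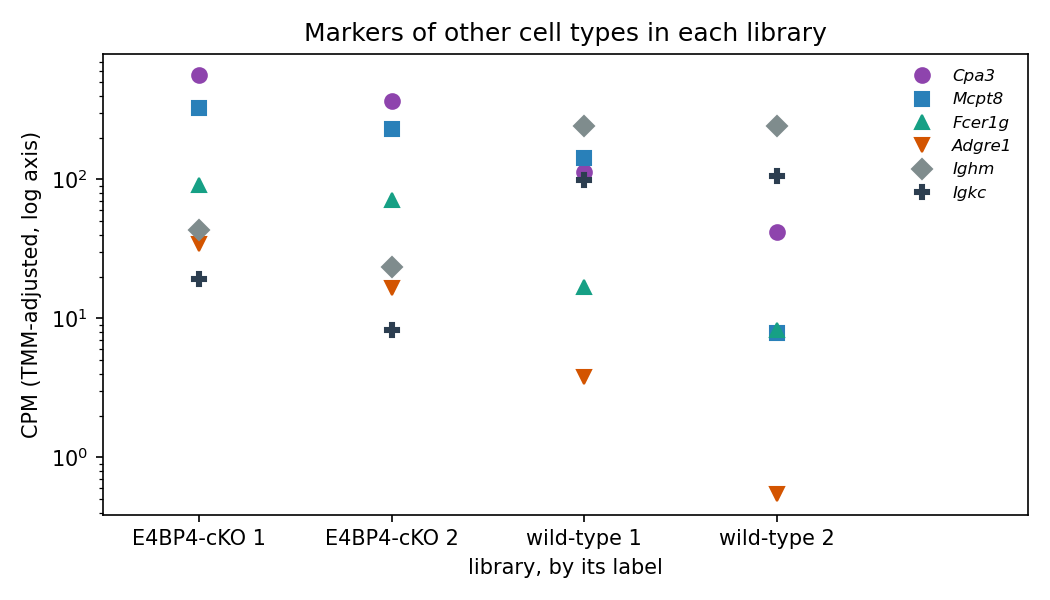
CPM of 6 markers of other cell types on a log axis, for each of the 4 libraries by label. Cpa3 and Fcer1g stood higher and Ighm and Igkc lower in both libraries labelled E4BP4-cKO, and Mcpt8 differed between the libraries labelled wild-type, at 142 and 7.81 CPM.

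The remaining lists were not called with all 4 libraries, TMM factors and the filter of filterByExpr. Immediate early and T cell receptor activation genes (camera adjusted p = 0.867) had Ier3, Dusp5, Fosl2 and Tnfaip3 higher and Egr3, Egr2 and Il2 lower among 23 (5 and 4 adjusted over the list alone), with Egr3 at 28.5 ± 3.08 against 118 ± 12.6 CPM and Egr2 at 32.8 ± 0.695 against 119 ± 20.97 CPM. Naive and central memory genes (camera adjusted p = 0.499) had 4 of 17 genes higher, among them Actn1, Ccr7 and Il7r, and 3 lower, Klf2, Igfbp4 and Lef1 (4 and 3 adjusted over the list alone). Chemokine receptors and trafficking genes (camera adjusted p = 0.499) had 4 of 22 genes higher, among them Itgb7, Ccr7 and Selplg, and 2 lower, among them Klf2 (6 and 3 adjusted over the list alone). Interferon-stimulated genes (camera adjusted p = 0.0636) had Oasl2, Oasl1, Rsad2 and Oas2 higher and Ifih1 lower among 29 (10 and 2 adjusted over the list alone). That list was called higher without E4BP4-cKO replicate 2 (adjusted p = 6.16e-06, 9 genes higher), without wild-type replicate 2 (adjusted p = 0.0319, 1 gene) and under scaling to total library size (adjusted p = 0.0283), while limma-voom called 0 of its genes higher. It had 1 higher and 4 lower without E4BP4-cKO replicate 1 and 0 called without wild-type replicate 1. Without E4BP4-cKO replicate 2, the numbers of higher genes of the 3 lists before it were 1, 0 and 0, and without wild-type replicate 1 they were 2, 1 and 1. The naive and central memory genes had 1 higher without E4BP4-cKO replicate 1, and 0 and 1 lower without E4BP4-cKO replicate 2 and wild-type replicate 1.

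Glycolysis and hypoxia genes (camera adjusted p = 0.341) had Slc2a3, Vegfa, Ero1l, Aldoc and Slc16a3 higher among 24 and 0 lower (5 and 0 adjusted over the list alone). Amino acid and unfolded protein response genes (camera adjusted p = 0.0883) had Trib3, Atf4 and Slc3a2 higher among 22 and 0 lower (8 and 2 adjusted over the list alone). Heat shock genes (camera adjusted p = 0.0873) had Hsph1 and Hspd1 lower among 12 and 0 higher (1 higher and 3 lower adjusted over the list alone). The p53 response and cell death genes (camera adjusted p = 0.867) had Bcl2l11 and Bcl2l1 higher and Bbc3, Phlda3 and Fas lower among 19 (3 and 4 adjusted over the list alone). Of 13 mitochondrially encoded mRNAs (camera adjusted p = 0.451), mt-Atp6 was higher (0 adjusted over the list alone). Of 25 nuclear oxidative phosphorylation genes and 19 circadian clock and D-box genes, a family that includes targets of the D-box element bound by E4BP4, 0 were called either way, also adjusted over the list alone (camera adjusted p = 0.499 and 0.209). Heat shock genes were called lower with a filter of at least 1 CPM in 2 libraries (adjusted p = 0.0276), and the mitochondrial mRNAs higher without E4BP4-cKO replicate 2 (adjusted p = 0.0294). Without E4BP4-cKO replicate 2, 2 glycolysis and hypoxia genes, 0 amino acid and unfolded protein response genes, 0 heat shock genes and 0 p53 response and cell death genes were called. Without wild-type replicate 1 these numbers were 2, 1, 0 and 2. The p53 response list had 1 higher without E4BP4-cKO replicate 1, and 1 higher and 1 lower without wild-type replicate 2. Without E4BP4-cKO replicate 1, 2 glycolysis genes and 1 amino acid response gene were lower, the latter list also having 1 lower without wild-type replicate 2. Of the mitochondrial mRNAs, 0 were higher when either library labelled wild-type was left out. Circadian clock and D-box genes had 2 higher without wild-type replicate 2, and 1 higher and 1 lower with DESeq2, and oxidative phosphorylation genes had 2 lower under scaling to total library size and 1 lower with DESeq2. At an unadjusted p under 0.05, edgeR passed 5538 genes in all.

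Xist, transcribed from the inactive X chromosome, and Y-linked genes differed between libraries of the same group. Xist had 21517 counts in E4BP4-cKO replicate 2 and 28571 in wild-type replicate 1, but 1 in E4BP4-cKO replicate 1 and 17 in wild-type replicate 2. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 4944 counts in wild-type replicate 2 and 0 in each of the other libraries, so that E4BP4-cKO replicate 1 had neither Xist nor these Y-linked reads beyond 1 count.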

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

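All alternatives were chosen before the data were examined, except the gene lists under DESeq2 size factors and upper-quartile factors. Nfil3 kept its direction and its call in all 12 alternative fits, with log2 fold changes from 3.69 to 3.94 when single libraries were left out. The counts of genes higher and lower in the libraries labelled E4BP4-cKO (1191 and 1013) were 1795 and 1657 with DESeq2, 2680 and 2237 without a filter, and 190 and 65 when tested against a 1.5-fold change, which asks for a larger effect. Scaling to total library size gave 1033 and 1636, so that 38.7% of calls were higher in place of 54.0%. Leaving out single libraries gave 246 to 954 genes higher and 74 to 806 lower. The lowest counts came without E4BP4-cKO replicate 2 (246 and 74), followed by wild-type replicate 1 (528 and 175), where the lone library is assumed to vary like the other group. Of the genes called with all libraries, 223 and 67 were still called without E4BP4-cKO replicate 2, and 0 were called with the opposite sign in any alternative. The fit without a filter had infinite prior degrees of freedom, so that each gene took the spread of the trend, against 3.44 with the filter, and its calls and p-values are not used as support. Scaling to total library size moved the median log2 fold change of all genes by -0.085.

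The 11 lists called became 0 with an estimated correlation and 1, the co-inhibitory receptors and Il10, with fry (adjusted p = 0.0292), 2 settings that recovered 0 of 10 simulated raised lists. Those simulated genes were independent and all raised by the same fold. The simulation therefore cannot show that the preset correlation holds for lists whose genes move together. Nor can it show how the 2 other settings perform on such lists or on larger changes. Leaving out single libraries gave 7 to 14 lists, with the lowest number without E4BP4-cKO replicate 1. In every setting, 0 lists called in both changed direction. The labels do not say that same-numbered libraries were paired. Their deviations from the group means correlated at only 0.0578, which gives no sign of pairing but cannot exclude it, as each group holds 2 libraries. With the replicate block, 1375 genes were higher and 1064 lower, Nfil3 had a log2 fold change of 3.81, and 13 lists were called, the 2 gained being the Treg programme (adjusted p = 0.0357) and the erythroid and platelet markers (adjusted p = 0.0305). With that block Pdcd1 was called (adjusted p = 0.0271), and Icos (adjusted p = 0.0561), Ahr, Il22, Ccl5, Oasl2, Rsad2 and mt-Atp6 were not. Among named genes, Cxcr5 turned to -0.031 under scaling to total library size, and ran from -0.23 (without E4BP4-cKO replicate 2) to 0.32 when single libraries were left out, with -0.18 without wild-type replicate 2. Pf4 ran from -0.38 to 3.41 and Hist1h2bc from -0.32 to 1.31, both lowest without E4BP4-cKO replicate 1, and Hist1h2ae from -0.99 to 0.054, highest without E4BP4-cKO replicate 2. With all libraries none of these 4 genes was called. In fits with all 4 libraries, lost calls had adjusted p from 0.0502 to 0.0949, among them Icos, Ahr, Il12rb1, Bcl2l1, mt-Atp6 and Rpl37 under total library size, and Wnt3, Oasl1, Oasl2 and Rsad2 with limma-voom. Depth was not the limit for Nfil3, but genes with fewer than 5 counts in a group have folds known only within wide intervals.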

Other observations

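Gene families were tested by symbol, after the data were seen, in 219 families with at least 8 tested members among 12383 protein-coding genes (438 Fisher exact tests, Benjamini-Hochberg adjusted). These tests treat genes as independent, although genes of a family can move together, so their p-values do not measure the spread between libraries. Among all tested protein-coding genes, including those without an official symbol, 1109 were higher and 954 lower. Genes named Cd, mostly surface molecules of blood cells, were over-represented among those higher in the libraries labelled E4BP4-cKO, with 23 of 75 higher and 3 lower (adjusted p = 2.54e-05). They included the stem and mast cell marker gene Cd34 at 18.01 ± 1.07 against 2.12 ± 0.617 CPM and the inhibitory receptor gene Cd200r1 at 35.15 ± 3.64 against 8.85 ± 2.805 CPM. Interleukin and interleukin receptor genes followed, with 14 of 53 higher and 4 lower (adjusted p = 0.0154), among them Il6 at 31.7 ± 13.04 against 1.82 ± 1.63 CPM, Il1b at 54.6 ± 46.7 against 1.52 ± 0.761 CPM and Il27 at 5.04 ± 0.214 against 0.196 ± 0.111 CPM. Matrix metalloproteinase genes had 6 of 13 higher and 1 lower (adjusted p = 0.0286), led by Mmp14 at 17.3 ± 5.11 against 1.15 ± 0.244 CPM. C-type lectin genes had 6 of 14 higher and 0 lower (adjusted p = 0.0406), among them Clec4n and Clec5a, which are myeloid receptor genes.

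In the other direction stood genes of replication, mitosis and the nuclear pore. Of the Mcm family, 7 of 10 were lower and 0 higher (adjusted p = 0.000279), with Mcm10 at 36.9 ± 4.64 against 75.5 ± 12.2 CPM. Kinesin genes had 9 of 31 lower and 1, Kif19a, higher (adjusted p = 0.0281), with Kif20a at 35.1 ± 1.21 against 85.4 ± 17.9 CPM. Nucleoporin genes had 7 of 20 lower and 0 higher (adjusted p = 0.0286), with Nup210 at 356 ± 0.433 against 605 ± 67.1 CPM. Zinc finger genes named Zfp were rarely called either way, with 9 of 338 higher and 11 lower. The adjusted p was 0.000864 for the depletion among higher genes and 0.0746 for that among lower genes. Under DESeq2 size factors, upper-quartile factors and total library size, the majority direction of the families other than Zfp stayed. Zfp had 10 higher and 10 lower genes under upper-quartile factors. Under total library size the numbers of lower genes rose to 13 of 20 for nucleoporins and to 17 of 338 for Zfp.

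The tests on RNA from other cells and on exchanged labels below were chosen only after the results were seen.

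Nfil3 was higher in both libraries labelled E4BP4-cKO, and RNA of mast cells, basophils, macrophages or dendritic cells stays open as its source. If all Nfil3 reads came with these cells, their 10 called markers would predict from 4.55 to 40.6 CPM of Nfil3 in the libraries labelled wild-type, against an observed 14.03 CPM, with 3 predictions within 1.5 times of it. These 10 are the granulocyte, myeloid and dendritic markers called higher in these same data, which leaves out the basophil gene Mcpt8. Mcpt8 differed far more between the libraries labelled wild-type than Nfil3 did, but it is a single marker over a single pair of libraries. Nfil3 was lower in replicate 1 than in replicate 2 of both groups (13.3 and 14.8 CPM, 179 and 216 CPM), while 8 of the 10 markers were higher there among the libraries labelled wild-type and 7 among the others, with Xcr1 lower in both, but each group is a single pair of libraries. Group labels exchanged between the genotypes cannot be told apart from a knockout allele that raises its own transcript, because the lowest ratio between the groups was 12.1 in Nfil3 and the table has 0 other marks of the genotype. Such an allele, with its transcript raised and its protein lost, is an untested hypothesis.

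The 2204 called genes could come from other differences between the mice than the genotype. Variants linked to the targeted locus that alter many genes near it are argued against. Of 139 tested genes within 10 Mb of Nfil3, 17 were called, against 2186 of 15363 elsewhere. The odds ratio was 0.840 (Fisher exact 95% interval 0.473 to 1.40). These shares cannot decide for single genes there, among them Slc25a48 (chromosome 13, 56438355 to 56474239), one of the largest decreases. Nor can they decide on effects of such variants on genes elsewhere. A difference in sex between the groups is argued against too. Each group had 1 library with Xist, and the ratio of the group means of Xist was 0.899. RNA from mast cells, basophils or myeloid cells stays open for the 1181 other genes called higher, although the labels name isolated naive CD4 T cells of the spleen as the starting cells, a selection expected to remove such cells. The observed difference between the libraries labelled wild-type, over that predicted from the 10 markers, had a median of -0.564 (quartiles -1.76 and 0.557), with 437 genes higher in replicate 1. Between the libraries labelled E4BP4-cKO the median was -0.249 (quartiles -0.840 and 0.463), and neither pair decides, since each holds 1 library on a side. A difference tied to the genotype stays open beside it, with its direction unknown while the labels of the 2 groups are in doubt.

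E4BP4-cKO replicate 1 had neither Xist nor reads of 4 Y-linked genes. A lost Xist row in a library with 2 X chromosomes is argued against. The 6 X-linked genes that escape silencing had a median ratio of 0.673 to E4BP4-cKO replicate 2, which expressed Xist. That median was 0.587 against the mean of the 2 libraries with Xist, with all 6 genes below 1, and it was 0.682 for wild-type replicate 2, the library with Y-linked reads. Lost Y-linked rows in a library with 1 X chromosome would give such values too, and were not tested. Cells with 1 X chromosome and without an expressed Y chromosome would also give them, a hypothesis found and tested on the same data. How such cells would have arisen was not tested.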
